A study of Mus musculus with 32 samples.

How the data were processed

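Messenger RNA levels were measured in 32 mouse livers with a 1-colour Affymetrix oligonucleotide array, to which biotin-labelled cRNA made from total liver RNA was hybridised. All mice were male C57BL/6 homozygous for a floxed Rps6 allele. The livers were taken at 0, 20, 30 or 40 h after partial hepatectomy, the surgical removal of part of the liver, after which the remaining tissue regrows. Mice with the Mx-Cre transgene (Cre plus) were compared with mice without it (Cre minus). The Mx promoter responds to interferon, and its Cre recombinase deletes floxed sequence when it is induced. Deletion was induced by injecting polyinosinic-polycytidylic acid, a synthetic double-stranded RNA that induces interferon, per the submitters' design text. The interval between injection and surgery, and whether Cre minus mice were injected too, are not given in the sources used here. The groups held 4 livers each, except 3 for Cre plus at 30 h and 5 for Cre plus at 40 h. The labels place the arrays in batches PHX2 and PHX3, and every group had arrays in both. Of the Cre minus livers at 40 h 1 was in PHX2, and of the Cre plus livers at 30 h 1 was in PHX3.

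The deposited table holds log2 expression values for 12488 probe sets, which the authors made with RMA, per the submitters' processing notes. The RMA version, and whether the batches were normalized together, are not given in the sources used here. The base of the logarithm was taken as 2 from the range of the values, 2.30 to 14.12, with array medians between 5.88 and 5.99. All columns of the table mapped to a sample. Probe sets were named through the platform annotation, updated to current symbols. Of 12422 probe sets other than the 66 AFFX controls, 10833 had 1 gene, 396 had several and 1193 were unnamed here. No gene was named from a probe set with several genes, except Rps6, whose probe set is also annotated to the pseudogene Rps6-ps4. For arrays, the number of arrays limits the precision.

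A probe set was tested when it lay above its own array's 30th percentile on at least 3 arrays, which kept 9249. Values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with the 8 groups and the batch as terms over all 32 arrays, so that the groups shared an estimate of the spread. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05, computed within each comparison. The comparisons were Cre plus against Cre minus at each time, 20, 30 and 40 h against 0 h within each genotype, and the interaction, which is the genotype difference at 20, 30 or 40 h minus that at 0 h. All p-values printed for genes and lists are adjusted. Differences are on the log2 scale with their standard error (SE), and group values are means with standard deviations (SD). Differences within PHX2 alone and PHX3 alone were computed beside the pooled ones. Tests on both sides of a shared group, such as the 3 times against 0 h, are not independent. The labels name no sham-operated livers. The time comparisons therefore cannot separate the removal of liver tissue from other effects of the operation or of elapsed time. The labels describe separate liver samples and do not say that each came from its own mouse, so the p-values measure the spread between these samples.

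There were 32 gene lists with 758 entries, of which 559 had a probe set of their own and 503 were tested. The pathway lists were p53 targets, ribosomal proteins without Rps6, ribosome biogenesis factors, G1 cyclins and regulators, DNA replication, mitosis, interferon response, acute phase, endoplasmic reticulum chaperones, ATF4 targets, NRF2 targets, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, cytochrome P450 drug metabolism, bile acid synthesis and transport, urea cycle and amino acid catabolism, gluconeogenesis, circadian clock and fetal liver genes. The cell type lists were hepatocyte secreted proteins, Kupffer cells and macrophages, neutrophils, T and NK cells, B cells, endothelial cells, stellate cells and fibroblasts, cholangiocytes and progenitors, erythroid cells, platelets, pancreatic acinar cells and adipocytes. Each gene entered by its probe set with the highest mean, 6786 genes in all. The lists of p53 and NRF2 targets shared 1 tested gene, as did those of NRF2 targets and fatty acid synthesis. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists within a comparison, and again with the correlation estimated from the data. Members past the threshold were counted over all probe sets and adjusted over the list alone.

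The genes named were chosen by a rule. It took 26 core genes, the called genes with the highest and lowest differences whose sign was the same in both batches (6 and 6 for each genotype comparison, 5 and 5 for Cre minus time courses and interactions, 3 and 3 for Cre plus time courses), and up to 4 members of each list described, by the size of the difference. Of the core genes 18 could be tested. Trp53, Bax, Ccnb1, Rpl11, Rpl5 and Saa1 had no probe set of their own, and Ccne2 and Mx1 did not pass the filter. The groups, comparisons, lists, naming rule and the alternatives to the fit were fixed before the data were examined.

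The alternatives tried were array weights, no batch term, a filter at the 50th percentile, no filter, arrays centred on their medians, quantile normalization, the replicate letter as a block beside batch, each array left out in turn, a fit on only the arrays of the groups compared, an intensity trend in eBayes, an estimated correlation in camera and the average of all probe sets of a gene. A fit without the 3 arrays that correlated under 0.95 with their own group, and a fit with the first residual component as a term, were added after the data were seen. The steps were tested on simulated data in which 200 of the 9249 probe sets were changed, by 0.5, 1 or 2 in log2. Of those changed by 1 the genotype comparisons at 0, 20, 30 and 40 h recovered 88.7, 89.0, 88.7 and 89.6%, and the 40 h interaction 76.4%. Of those changed by 0.5 they recovered 58.2, 60.0, 51.3 and 62.7%, and the interaction 33.4%. Each probe set was drawn with the same spread on all arrays, whereas the real livers varied less at 0 h than later. These shares therefore do not show how recovery differs between the times in the real data. In camera's test for the 40 h genotype comparison over 6786 genes, 20 of 20 lists shifted by 0.5 were called and 0 of 400 unshifted lists. The simulated probe sets were drawn independently of one another. The simulations therefore cannot tell whether the preset correlation is high enough for the real lists. Figures were drawn in Python 3.11.15.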

Results

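Gene expression was measured in 32 livers of male mice with floxed Rps6, the gene of ribosomal protein S6 of the small ribosomal subunit. The design compared livers in which Rps6 had been conditionally deleted (Cre plus) with floxed livers lacking the recombinase (Cre minus). It also followed both genotypes after partial hepatectomy, when the remaining liver regrows, to see which responses need Rps6. There were 4 Cre minus and 4 Cre plus livers at 0 h, 4 and 4 at 20 h, 4 and 3 at 30 h, and 4 and 5 at 40 h. Arrays of a group correlated with one another at a mean r of 0.990 in Cre minus and 0.990 in Cre plus livers at 0 h, 0.971 and 0.969 at 20 h, 0.962 and 0.963 at 30 h, and 0.982 and 0.957 at 40 h. The first 4 principal components held 30.5, 17.3, 11.3 and 7.01% of the variance. Batch itself changed 2494 probe sets, 904 of them higher and 1590 lower in PHX3.

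The Rps6 probe set lay far lower in Cre plus livers at every time. In Cre minus livers its mean log2 value was 11.11 ± 0.13 at 0 h, 11.57 ± 0.17 at 20 h, 11.47 ± 0.12 at 30 h and 11.35 ± 0.10 at 40 h (SD). In Cre plus livers it was 6.81 ± 0.44, 7.23 ± 0.35, 6.89 ± 0.33 and 7.21 ± 0.22. The 16 Cre minus livers ranged from 10.99 to 11.82 and the 16 Cre plus livers from 6.24 to 7.69, with no overlap. The difference was −4.30 at 0 h (SE 0.15, adjusted p = 3.85e-17, 19.8-fold lower), −4.34 at 20 h (SE 0.15, adjusted p = 3.14e-17), −4.55 at 30 h (SE 0.17, adjusted p = 7.37e-17) and −4.10 at 40 h (SE 0.15, adjusted p = 3.74e-17). Within PHX2 it was −4.58, −4.50, −4.59 and −4.13 at the successive times, and within PHX3 −4.03, −4.18, −4.49 and −4.14. The interaction with time did not pass at 20 h (−0.03, adjusted p = 0.9997), 30 h (−0.24, adjusted p = 0.975) or 40 h (0.20, adjusted p = 0.9992). The probe set is shared with a pseudogene, and its place relative to the deleted exons is not given in the sources used here.

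**Figure D1:**
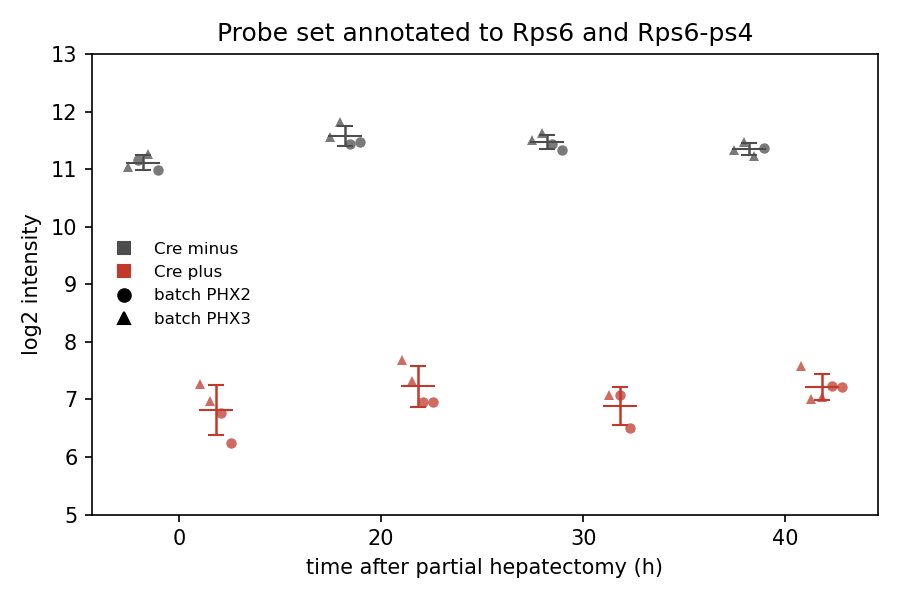
The log2 intensity of the Rps6 probe set is plotted for each liver by time after partial hepatectomy and genotype, with circles for batch PHX2, triangles for PHX3, a dash at the group mean and bars of 1 SD. Cre minus livers lie between 10.99 and 11.82, and Cre plus livers between 6.24 and 7.69.

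At 0 h, few genes other than Rps6 were called between the genotypes. The SD of the difference between arrays of a group reached 0.261 and 0.263 at 0 h, and 0.373 to 0.581 later. The shared estimate of the spread takes in the later livers, so the test at 0 h may be too strict. The 0 h arrays alone gave 26 calls and array weights 55, against 6 in the fit reported. Notch1, a receptor of cell fate signalling, was higher in Cre plus livers by 0.83 (SE 0.09, adjusted p = 4.08e-06), and by 0.68 within PHX2 and 0.98 within PHX3. Ephx1, which encodes microsomal epoxide hydrolase, was higher by 0.74 (SE 0.13, adjusted p = 0.00836), and Zmat3, an RNA-binding zinc finger protein induced by p53, by 0.64 (SE 0.12, adjusted p = 0.0341). With 4 livers in each group, 6 probe sets were called, 4 higher and 2 lower. The others were Rps6, a second Cdkn1a probe set (2.13, adjusted p = 0.0403) and a probe set shared by Gm15421, Rpl22l1 and Orc5 (−1.65), the last 2 chosen after their values were seen. Of the 18 p53 targets tested, 2 rose and 16 did not pass, 7 were higher when adjusted over the list alone, and 16 had a positive difference. The list's median was 0.25 (camera adjusted p = 2.03e-19, and adjusted p = 2.21e-08 with an estimated correlation), or 0.24 within PHX2 and 0.32 within PHX3. Cdkn1a, the cell cycle inhibitor p21, had a difference of 0.90, Ccng1 of 0.89 and Phlda3, an Akt inhibitor induced by p53, of 0.83, none past the threshold over all probe sets.

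Kupffer cell and macrophage markers were lower as a list in Cre plus livers at 0 h. All 12 members had a negative difference. Their median was −0.43 (camera adjusted p = 4.13e-20, and adjusted p = 0.0153 with an estimated correlation). It was −0.63 within PHX2 and −0.35 within PHX3. None of the 12 passed over all probe sets, and 6 were lower when adjusted over the list alone. Examples were Clec4f, a Kupffer cell lectin, at −0.80, and C1qb, a chain of complement C1q, at −0.70. Endothelial markers had a median of 0.10 with no member past either threshold (camera adjusted p = 8.71e-04, and adjusted p = 0.0229 with an estimated correlation). The other 7 lists called lost their call when the correlation was estimated. These were DNA replication (median −0.16, adjusted p = 2.94e-12, adjusted p = 0.104 with an estimated correlation), mitosis (−0.14, adjusted p = 9.47e-10, then 0.288), ribosomal proteins (0.10, adjusted p = 1.56e-05, then 0.394), ribosome biogenesis factors (0.09, adjusted p = 0.0107, then 0.706), endoplasmic reticulum chaperones (−0.15, adjusted p = 0.00275, then 0.617), fatty acid synthesis (−0.22, adjusted p = 0.0127, then 0.394) and B cells (−0.08, adjusted p = 0.0280, then 0.394). Leaving out 1 of Cre minus B or C or Cre plus B or D left 3 probe sets called, 1 higher and 2 lower, and ended the call of Ephx1 (p up to 0.0991, without Cre plus B). The second Cdkn1a probe set was not called either when any 1 of these 4 was left out. Zmat3 lost its call without any 1 of the 8 livers, with p up to 0.232 without Cre minus A, and a fit on the 0 h arrays alone called 26 probe sets. List calls lost on leaving out 1 liver were those of B cells (p up to 0.367, without Cre plus B), fatty acid synthesis (0.588, Cre plus D), ribosome biogenesis factors (0.340, Cre plus B) and endoplasmic reticulum chaperones (0.0633, Cre minus B).

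At 20 h, Cre plus livers had lower levels of macrophage genes and of globins and higher levels of a few p53-induced and other genes. Cd5l, secreted by macrophages, differed by −1.87 (SE 0.33, adjusted p = 0.00550), Clec4f by −1.51 (SE 0.22, adjusted p = 7.86e-04) and C1qb by −1.12 (SE 0.19, adjusted p = 0.00247). Fabp7, a fatty acid binding protein, differed by −1.59 (SE 0.23, adjusted p = 6.64e-04). The globin genes Hba-a1 and Hbb-b2 differed by −2.59 (SE 0.58, adjusted p = 0.0482) and −2.53 (SE 0.56, adjusted p = 0.0424), or by −1.03 and −0.73 within PHX2 and −4.15 and −4.33 within PHX3. Among the genes that were higher were Ifrd1, a transcriptional co-regulator, by 1.66 (SE 0.31, adjusted p = 0.00793), and Phlda3 by 0.97 (SE 0.17, adjusted p = 0.00589). Ephx1 was higher by 0.60 (SE 0.13, adjusted p = 0.0313) and Aldh2, the mitochondrial aldehyde dehydrogenase, by 0.50 (SE 0.09, adjusted p = 0.00793). In all, 27 probe sets were called among 4 and 4 livers, 5 higher and 22 lower, and none of the 17 tested core genes other than Rps6 was among them. Within the batches alone, 1 probe set was called in PHX2 and 289 in PHX3, and the differences of all probe sets correlated at −0.20 between the batches. In the pooled fit limma gave 409 probe sets at an unadjusted p under 0.05, where 462.4 are expected by chance.

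Of the 12 Kupffer cell and macrophage markers at 20 h, 5 fell and 7 did not pass, and 10 were lower when adjusted over the list alone. Their median was −0.84 (camera adjusted p = 7.89e-29, and adjusted p = 0.00232 with an estimated correlation). It was −0.59 within PHX2 and −1.14 within PHX3. Of the 18 p53 targets, 2 rose, Phlda3 and Ephx1, and 5 were higher when adjusted over the list alone. Their median was 0.22 (camera adjusted p = 5.55e-06, and adjusted p = 4.46e-04 with an estimated correlation). Calls of 9 further lists were lost with an estimated correlation. Ribosome biogenesis factors had a median of 0.15 (adjusted p = 4.78e-04, adjusted p = 0.592 with an estimated correlation), with −0.16 within PHX2 and 0.58 within PHX3. Endoplasmic reticulum chaperones had −0.34 (adjusted p = 0.00101, then 0.592), P450 enzymes 0.17 (adjusted p = 0.00153, then 0.190), DNA replication −0.14 (adjusted p = 0.0123, then 0.633) and fatty acid oxidation −0.22 (adjusted p = 0.0123, then 0.592). Mitosis had −0.08 (adjusted p = 0.0359, then 0.713), stellate cells 0.09 (adjusted p = 0.0359, then 0.592), the urea cycle 0.11 (adjusted p = 0.0359, then 0.592) and the circadian clock 0.25 (adjusted p = 0.0447, then 0.300). Calls of Ephx1, Hba-a1, Hbb-b2 and Aldh2 were lost on leaving out any of several livers, with p up to 0.152 (without Cre minus A), 0.231 (without Cre minus A), 0.219 (without Cre plus A) and 0.0730 (without Cre plus D), and that of Ifrd1 without Cre plus B (adjusted p = 0.0511). Of the 11 lists only p53 targets, the macrophage markers and P450 enzymes kept their call under each omission. The p of the others reached 0.427 for DNA replication (without Cre minus B), 0.307 for the clock (Cre plus C), 0.393 for the chaperones (Cre minus A) and 0.885 for fatty acid oxidation (Cre plus D). It reached 0.194 for mitosis (Cre plus D), 0.211 for ribosome biogenesis (Cre plus B), 0.302 for stellate cells (Cre minus B) and 0.612 for the urea cycle (Cre plus D). Without Cre plus D 17 probe sets were called, and with the 20 h arrays alone 1.

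At 30 h, 4 of the 18 p53 targets tested were higher in Cre plus livers, Btg2, Plk2, Mdm2 and Ephx1. Btg2, an antiproliferative gene, was higher by 1.41 (SE 0.30, adjusted p = 0.0401), Plk2, a polo-like kinase, by 0.92 (SE 0.16, adjusted p = 0.00929) and Mdm2, the ubiquitin ligase of p53, by 0.74 (SE 0.16, adjusted p = 0.0401). Alpl, tissue-nonspecific alkaline phosphatase, was higher by 1.88 (SE 0.39, adjusted p = 0.0401), Ifrd1 by 1.75 (SE 0.34, adjusted p = 0.0251) and Wdr43, a factor of small-subunit ribosome assembly, by 0.82 (SE 0.17, adjusted p = 0.0401). Among the genes that were lower, Cd5l differed by −1.74 (SE 0.36, adjusted p = 0.0401), Clec4f by −1.15 (SE 0.24, adjusted p = 0.0406) and Plpp3, a lipid phosphatase, by −1.46 (SE 0.22, adjusted p = 0.00132). Dipk2a (−1.02), 1810058I24Rik (−0.86) and Ormdl1, a regulator of sphingolipid synthesis (−0.74), were also lower. In all, 26 probe sets were called among 4 Cre minus and 3 Cre plus livers, 12 higher and 14 lower, which became 12 and 8 with arrays centred and 16 and 10 after quantile normalization. Within the batches 2 were called in PHX2 and 20 in PHX3. In the arrays of this time the Actb 3′ minus 5′ difference, a measure of RNA integrity, was 1.07 ± 0.22 in Cre minus and 0.84 ± 0.04 in Cre plus livers. Cre minus C and Cre plus A of this time correlated with their own groups at only 0.945 and 0.9495. Without them and Cre plus D of 40 h, the genotype comparison at 30 h called 950 probe sets, 421 higher and 529 lower. Cre plus A was the only PHX3 liver of its group. This fit therefore left 2 Cre plus livers, both of PHX2, and the genotypes were unevenly spread over the batches.

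Of the 18 p53 targets at 30 h, 4 rose, and 7 were higher and 1 lower when adjusted over the list alone. Their median was 0.33 (camera adjusted p = 5.44e-05, and adjusted p = 0.00248 with an estimated correlation). It was 0.19 within PHX2 and 0.35 within PHX3. The other 9 calls were lost with an estimated correlation. Of the 39 DNA replication genes 1 fell and 16 were lower when adjusted over the list alone. Their median was −0.36 (camera adjusted p = 8.05e-13, adjusted p = 0.160 with an estimated correlation). It was −0.26 within PHX2 and −0.41 within PHX3. Kupffer cell and macrophage markers had 2 members lower, 6 over the list alone, and a median of −0.45 (adjusted p = 4.55e-08, adjusted p = 0.292 with an estimated correlation). Mitosis genes had a median of −0.24 (adjusted p = 1.23e-07, then 0.417), endoplasmic reticulum chaperones −0.46 (adjusted p = 4.93e-05, then 0.417), NRF2 targets 0.23 (adjusted p = 0.005, then 0.417) and ribosome biogenesis factors 0.12 (adjusted p = 0.00147, then 0.586). The urea cycle had 0.16 (adjusted p = 0.0066, then 0.417), fatty acid oxidation −0.34 (adjusted p = 0.0128, then 0.578) and the circadian clock 0.12 (adjusted p = 0.0474, then 0.292). Only Rps6 and Plpp3 of the 14 named genes called kept their call under the omission of each of the 7 livers, and the p of the others rose. It reached 0.0879 for Plk2, 0.165 for Mdm2, 0.165 for Cd5l and 0.130 for 1810058I24Rik without Cre plus A, and 0.172 for Btg2 without Cre plus C. Without Cre minus D it reached 0.240 for Alpl, 0.248 for Clec4f, 0.163 for Dipk2a, 0.163 for Ifrd1, 0.249 for Ormdl1, 0.204 for Wdr43 and 0.199 for Ephx1. List calls lost were those of NRF2 targets (adjusted p = 0.423), ribosome biogenesis (0.137) and the urea cycle (0.238) without Cre plus A, fatty acid oxidation (0.126) without Cre plus B and the clock (0.113) without Cre plus C. The count fell to 4 without Cre minus A, 6 without Cre minus D, and 11, 5 and 10 without Cre plus A, B and C, rose to 266 without Cre minus C, and was 4 with the 30 h arrays alone.

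At 40 h, genes of DNA synthesis and mitosis were far lower in Cre plus livers. Stmn1, which destabilises microtubules, differed by −3.29 (SE 0.30, adjusted p = 3.38e-08), Rrm2, a subunit of ribonucleotide reductase, by −2.79 (SE 0.26, adjusted p = 4.33e-08) and Mcm5, part of the replicative helicase, by −2.45 (SE 0.29, adjusted p = 1.50e-06). Cdk1, the kinase of mitotic entry, differed by −2.38 (SE 0.23, adjusted p = 4.33e-08), Pcna, the sliding clamp of DNA polymerase, by −1.95 (SE 0.19, adjusted p = 6.92e-08), Top2a, a topoisomerase, by −1.22 (SE 0.14, adjusted p = 1.72e-06) and Ccna2, cyclin A2, by −0.82 (SE 0.09, adjusted p = 4.66e-07). D17H6S56E-5 differed by −3.41, and the globin genes Hbb-b2 and Hba-a1 by −3.13 (SE 0.53, adjusted p = 3.41e-04) and −3.12 (SE 0.55, adjusted p = 5.94e-04). The genes that were higher included Ifrd1 by 2.04 (SE 0.30, adjusted p = 3.74e-05), Eif5, a translation initiation factor, by 1.72 (SE 0.20, adjusted p = 1.50e-06), and Gadd45g, a growth arrest gene, by 1.73 (SE 0.39, adjusted p = 0.00637). Slc25a47, a mitochondrial carrier, was higher by 1.90 (adjusted p = 0.0311), Retreg1, a receptor for autophagy of the endoplasmic reticulum, by 1.56 (adjusted p = 0.0497), and Nudt4, a diphosphoinositol phosphatase, by 1.24 (adjusted p = 0.0106). Mdm2 was higher by 0.87 (SE 0.14, adjusted p = 1.31e-04) and Cdkn1a by 1.14 (SE 0.33, adjusted p = 0.0424), or by 1.76 on its second probe set (SE 0.40, adjusted p = 0.00683). The other core genes did not pass, with differences of 0.80 for Ccng1 (adjusted p = 0.0738), 0.85 for Myc (adjusted p = 0.192), −0.29 for Ccnd1 (adjusted p = 0.854), −0.14 for Ccne1 (adjusted p = 0.489), −0.27 for Mki67 (adjusted p = 0.342), −0.10 for Alb (adjusted p = 0.503), −0.50 for Cyp7a1 (adjusted p = 0.706), 0.05 for Hspa5 (adjusted p = 0.968) and −0.02 for Afp (adjusted p = 0.965). The Mki67 probe set lay at 4.76 in Cre plus and 5.01 in Cre minus livers, under the array medians. Its change from 0 to 40 h in Cre minus livers was not called either (0.22, adjusted p = 0.4875).

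In all, 495 probe sets were called at 40 h among 4 Cre minus and 5 Cre plus livers, 211 higher and 284 lower, and 89 of them differed at least 2-fold, 18 higher and 71 lower. The balance of all calls turned to 450 higher and 411 lower with array weights, 351 and 311 without the 3 arrays correlating under 0.95 with their group and 413 and 407 with the first residual component as a term. The sign was the same in both batches for 493 of the 495, with 12 called within PHX2, where Cre minus had 1 liver, and 431 within PHX3. Without Cre minus A 295 were called, without Cre minus C 318, and with the 40 h arrays alone 195. Of the 37 named genes called, 28 kept their call under the omission of each of the 9 livers. The calls lost were those of Cdkn1a (p up to 0.150, without Cre minus D), Retreg1 (0.133, without Cre minus C), Slc25a47 (0.110, without Cre minus A), Tsr1 (0.133, without Cre minus B), Psmb8 (0.217, without Cre minus C), E2f1 (0.0931, without Cre minus A), Gnl3 (0.0727, without Cre minus D), Rps19 (0.0753, without Cre minus C) and Rpl32 (0.0567, without Cre minus A).

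Of the 39 DNA replication genes at 40 h, 30 fell and 9 did not pass, 33 were lower when adjusted over the list alone. Their median was −0.82 (camera adjusted p = 3.04e-48, and adjusted p = 1.52e-04 with an estimated correlation). It was −0.96 within PHX2 and −0.83 within PHX3. Fen1, the flap endonuclease, differed by −1.79 (SE 0.31, adjusted p = 4.11e-04). Of the 35 mitosis genes, 29 fell and 30 were lower over the list alone. Their median was −1.09 (camera adjusted p = 1.32e-61, and adjusted p = 1.52e-04 with an estimated correlation). It was −0.77 within PHX2 and −1.25 within PHX3. Among them, Cdc20, an activator of the anaphase-promoting complex, differed by −2.23 (SE 0.18, adjusted p = 3.83e-09) and the mitotic kinase Aurka by −2.13 (SE 0.18, adjusted p = 7.36e-09). Of the 13 G1 cyclins and regulators, 6 fell, 6 were lower and 1 higher over the list alone. Their median was −0.29 (camera adjusted p = 1.14e-05, and adjusted p = 0.0259 with an estimated correlation). It was −0.40 within PHX2 and −0.16 within PHX3. Those that fell included Cdkn2c, an inhibitor of Cdk4 and Cdk6 (−0.95, adjusted p = 9.91e-06), the pocket protein gene Rbl1 (−0.79, adjusted p = 1.03e-04) and the transcription factor gene E2f1 (−0.40, adjusted p = 0.0216). Of the 18 p53 targets, 6 rose and 8 were higher over the list alone. Their median was 0.41 (camera adjusted p = 2.54e-07, and adjusted p = 1.52e-04 with an estimated correlation). It was 0.52 within PHX2 and 0.33 within PHX3. Besides Mdm2 and Cdkn1a, Phlda3 was higher by 0.92 (adjusted p = 7.11e-04).

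**Figure D2:**
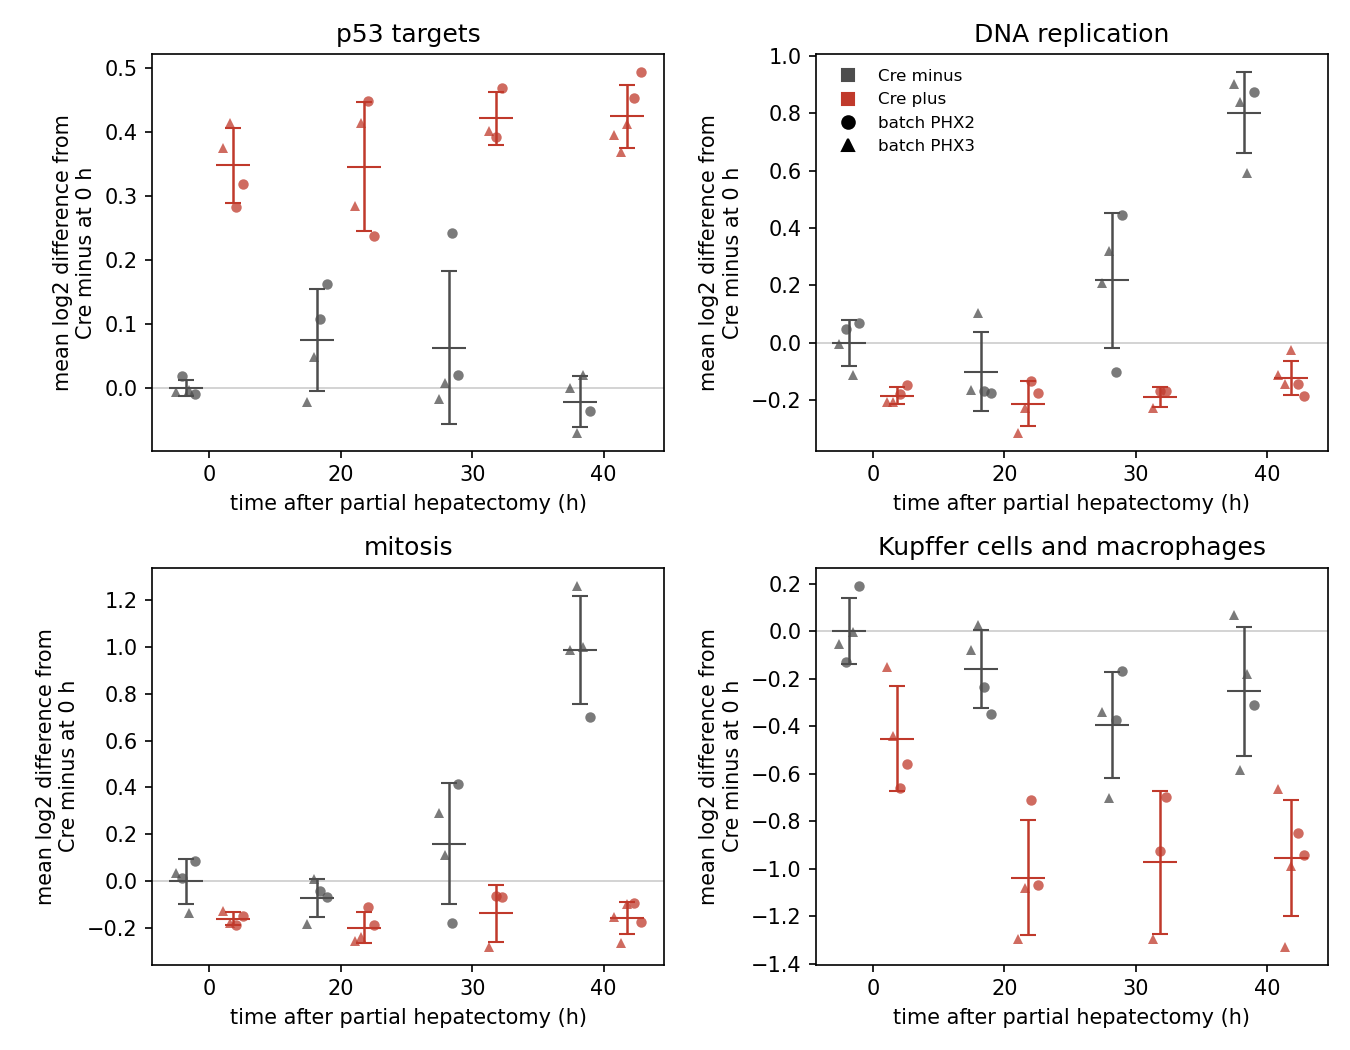
Each panel plots, for 1 gene list, the mean log2 difference of its members from the Cre minus livers at 0 h, per liver and by time after partial hepatectomy, with the group mean and bars of 1 SD. At 40 h DNA replication genes averaged 0.80 in Cre minus and −0.12 in Cre plus livers and mitosis genes 0.99 and −0.16. Over all times p53 targets averaged 0.35 to 0.43 in Cre plus and −0.02 to 0.07 in Cre minus livers. Kupffer cell markers averaged −0.45 to −1.04 in Cre plus livers, and in Cre minus livers −0.16, −0.40 and −0.25 at 20, 30 and 40 h.

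The remaining 5 lists called at 40 h lost their call with an estimated correlation. Of the 12 Kupffer cell and macrophage markers, 7 fell and 11 were lower over the list alone. Their median was −0.66 (camera adjusted p = 1.31e-10, adjusted p = 0.0886 with an estimated correlation). It was −0.56 within PHX2 and −0.76 within PHX3. Clec4f differed by −1.43 (SE 0.21, adjusted p = 5.80e-05), Cd5l by −1.43 (SE 0.32, adjusted p = 0.00581), C1qb by −0.94 (adjusted p = 0.00124) and C1qc by −0.84 (adjusted p = 7.76e-04). Of the 39 ribosome biogenesis factors, 8 rose and 17 were higher over the list alone. Their median was 0.39 (camera adjusted p = 6.23e-11, adjusted p = 0.167 with an estimated correlation). It was 0.31 within PHX2 and 0.45 within PHX3. Nucleolin (Ncl), which binds ribosomal RNA precursors, was higher by 1.17 (SE 0.24, adjusted p = 0.0035), Tsr1 by 0.83 (adjusted p = 0.0457) and Gnl3 by 0.82 (adjusted p = 0.0216), while Npm1 had a difference of 0.83 (adjusted p = 0.0551). Among the 28 ribosomal proteins other than Rps6, 1 rose (Rps19, 0.38, adjusted p = 0.0130) and 1 fell (Rpl32, −0.43, adjusted p = 0.0132), and over the list alone 5 were higher and 1 lower. The median was 0.11 (camera adjusted p = 0.0296, adjusted p = 0.717 with an estimated correlation). The call was lost after quantile normalization and without Cre minus A (adjusted p = 0.245), Cre minus C, Cre plus C or Cre plus E. Endoplasmic reticulum chaperones had 1 member lower (Sec61b, −0.76, adjusted p = 0.00645) and a median of −0.29 (camera adjusted p = 0.0376, adjusted p = 0.717 with an estimated correlation), which was lost without Cre minus D, Cre plus A (adjusted p = 0.357) or Cre plus C. Interferon response genes had 1 of 25 members lower (Psmb8, an immunoproteasome subunit, −0.77, adjusted p = 0.0487) and a median of −0.17 (camera adjusted p = 0.0432, adjusted p = 0.717 with an estimated correlation). It was 0.08 within PHX2 and −0.38 within PHX3, which was lost without Cre minus A, Cre minus C (adjusted p = 0.257) or Cre plus B.

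Other pathways and cell types were not called at 40 h. Gluconeogenesis genes had a median of 0.48 (camera adjusted p = 0.0614), hepatocyte secreted proteins −0.13 (adjusted p = 0.0907), NRF2 targets 0.18 (adjusted p = 0.150), the urea cycle 0.25 (adjusted p = 0.195), the circadian clock 0.17 (adjusted p = 0.214) and acute phase genes 0.05 (adjusted p = 0.305). ATF4 targets had a median of 0.10 (adjusted p = 0.318), cholesterol synthesis −0.32 (adjusted p = 0.426) with 0.21 within PHX2 and −0.59 within PHX3, fatty acid synthesis −0.08 with a mean of −0.26 (adjusted p = 0.502), fetal liver genes 0.01 (adjusted p = 0.678) and bile acid synthesis and transport 0.00 (adjusted p = 0.887). Fatty acid oxidation had a median of −0.10 and a mean of 0.01 (adjusted p = 0.502), and P450 enzymes a median of −0.01 and a mean of 0.10 (adjusted p = 0.704). Erythroid markers had a median of −0.05 and a mean of −0.57 over 6 members (adjusted p = 0.318), with Hba-a1 at −3.12. Their means were −0.18, −0.45 and −0.42 at 0, 20 and 30 h. Of the other cell types, T and NK cells −0.08 (adjusted p = 0.333), B cells −0.08 (adjusted p = 0.335), cholangiocytes 0.07 (adjusted p = 0.426), stellate cells 0.04 (adjusted p = 0.502), endothelial cells 0.02 (adjusted p = 0.502), pancreatic acinar cells −0.06 (adjusted p = 0.502), neutrophils −0.04 (adjusted p = 0.504) and platelets −0.07 (adjusted p = 0.595). Adipocyte markers had a median of 0.01 and a mean of 0.74 over 3 members (adjusted p = 0.608), with Cidec at 2.27 (adjusted p = 0.217). The Gapdh 3′ minus 5′ difference, a measure of RNA integrity, differed between genotypes by 0.09, 0.07, −0.00 and 0.07 at 0, 20, 30 and 40 h, and that of Actb by 0.04, 0.02, −0.22 (SE 0.08) and −0.03.

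Across the 4 times, Rps6, Ephx1 and the probe set shared by Gm15421, Rpl22l1 and Orc5 were called at each, and Clec4f, Cd5l, Ifrd1 and Plpp3 at 3. A second probe set of Aldh2 was called at 3 times too, while the one reported at 20 h did not pass at 30 h (0.34, adjusted p = 0.146). Ephx1 was higher by 0.74, 0.60, 0.63 and 0.63 at the successive times. The genotype calls at 20 and 40 h shared 20 probe sets in the same direction where 0.790 would be shared by independent lists, those at 30 and 40 h 15 where 0.704 would, and those at 20 and 30 h 8 where 0.0398 would. None was shared in opposite directions. These comparisons used different arrays, although all share the batch term and the estimate of the spread.

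In Cre minus livers 20 h after hepatectomy, Mt1, Mt2 and Lcn2 had risen and 12 of 16 cholesterol synthesis genes had fallen. The metallothionein genes Mt2 and Mt1 rose by 3.82 (SE 0.44, adjusted p = 1.36e-05) and 3.61 (SE 0.50, adjusted p = 1.48e-04), Lcn2, lipocalin 2, by 3.56 (SE 0.59, adjusted p = 7.54e-04), Cidec, a lipid droplet protein gene, by 3.66 (SE 1.03, adjusted p = 0.0291) and Cyp4a10, a fatty acid hydroxylase, by 3.55 (SE 0.95, adjusted p = 0.0218). The steroid dehydrogenase genes Hsd3b5 and Hsd3b2 fell, with −3.85 (SE 0.77, adjusted p = 0.00395) and −3.08 (SE 0.54, adjusted p = 0.00117). Keg1 (−3.08, SE 0.45, adjusted p = 1.71e-04) and the sterol synthesis genes Idi1 (−2.70, adjusted p = 0.00826) and Sc5d (−2.70, adjusted p = 9.46e-04) fell too. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 2.50 (SE 0.54, adjusted p = 0.00638). Of the 16 cholesterol synthesis genes 12 fell and 15 were lower over the list alone. Their median was −1.57 (camera adjusted p = 1.86e-11, adjusted p = 0.187 with an estimated correlation). Of the 39 ribosome biogenesis factors 11 rose, and 21 were higher and 1 lower over the list alone. Their median was 0.42 (camera adjusted p = 2.02e-14, adjusted p = 0.187 with an estimated correlation). Acute phase genes had 8 members higher and 1 lower (median 0.32, adjusted p = 1.18e-07, then 0.187), fatty acid synthesis 7 lower (−0.74, adjusted p = 0.00199, then 0.228), fatty acid oxidation 5 higher (0.64, adjusted p = 5.94e-05, then 0.232), interferon response 6 lower (−0.44, adjusted p = 7.98e-05, then 0.361) and ribosomal proteins 7 higher (0.25, adjusted p = 1.72e-06, then 0.228). Calls of Cidec and Cyp4a10 were lost on leaving out some livers, with p up to 0.104 (without 20 h D) and 0.0937 (without 0 h A). In all, 682 probe sets were called among 4 and 4 livers, 308 higher and 374 lower, with 89 called within PHX2 and 243 within PHX3. The balance turned to 1058 higher and 1037 lower with array weights and 786 and 683 with only the arrays compared. It was 523 and 511 without the 3 arrays correlating under 0.95 with their group. Without each of the 0 h livers A to D the count was 334, 420, 393 and 413, and without the 20 h livers B, C and D 390, 345 and 331.

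At 30 h in Cre minus livers Mt2 had risen by 3.89 (SE 0.44, adjusted p = 2.19e-05), Lcn2 by 3.57 (SE 0.59, adjusted p = 0.00113), Mt1 by 3.47 (SE 0.50, adjusted p = 3.85e-04), the apolipoprotein gene Apoa4 by 2.33 (SE 0.36, adjusted p = 5.27e-04) and Gadd45g by 2.09 (SE 0.41, adjusted p = 0.00543). Those that fell included Inmt, an N-methyltransferase (−3.09, SE 0.61, adjusted p = 0.00568), Hsd3b5 (adjusted p = 0.0318) and Car3, a carbonic anhydrase (−2.93, SE 0.74, adjusted p = 0.0282). Keg1 (−2.66, adjusted p = 0.00136) and Thrsp, a lipogenesis gene (−2.63, SE 0.63, adjusted p = 0.0238), fell as well. Rrm2 rose by 1.07 (SE 0.28, adjusted p = 0.0323), but 2 of the 39 DNA replication genes passed, with 11 higher and 1 lower over the list alone and a median of 0.19 (camera adjusted p = 3.38e-06, adjusted p = 0.226 with an estimated correlation). Bile acid synthesis and transport, with 3 of 12 members lower and 7 over the list alone, had a median of −0.62 (camera adjusted p = 5.55e-04, and adjusted p = 0.0213 with an estimated correlation). It was the only 1 of 15 list calls held with an estimated correlation. In all, 290 probe sets were called among 4 and 4 livers, 93 higher and 197 lower, with 6 called within PHX2 and 120 within PHX3. Without the 0 h livers A to D the count was 88, 138, 101 and 179, and without the 30 h livers B and C 114 and 191. Hsd3b5, Car3, Thrsp and Rrm2 lost their call on leaving out some livers, with p up to 0.112 (without 0 h A), 0.102 (without 30 h A), 0.0933 (without 0 h C) and 0.110 (without 0 h C).

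At 40 h in Cre minus livers the genes of DNA replication and mitosis had risen. Rrm2 rose by 2.76 (SE 0.28, adjusted p = 2.53e-07), Stmn1 by 2.75 (SE 0.32, adjusted p = 2.47e-06) and Cdk1 4.91-fold (adjusted p = 3.88e-07). Mcm5 rose by 2.18 (SE 0.30, adjusted p = 3.25e-05), Cdc20 by 2.17 (SE 0.19, adjusted p = 6.5e-08) and Pcna by 1.72 (SE 0.20, adjusted p = 2.59e-06). Top2a rose by 1.16 (adjusted p = 1.47e-05) and Ccna2 by 0.72 (adjusted p = 1.54e-05). Of 39 DNA replication genes 27 rose and 31 were higher over the list alone. Their median was 0.73 (camera adjusted p = 8.06e-41, and adjusted p = 8.58e-04 with an estimated correlation). It was 0.61 within PHX2 and 0.74 within PHX3. Of 35 mitosis genes 27 rose and 28 were higher over the list alone. Their median was 0.92 (camera adjusted p = 8.36e-49, and adjusted p = 8.58e-04 with an estimated correlation). It was 0.65 within PHX2 and 0.97 within PHX3. G1 cyclins and regulators had 5 of 13 members higher and a median of 0.33 (adjusted p = 6.73e-08, and adjusted p = 0.00487 with an estimated correlation), and bile acid synthesis and transport 3 of 12 lower and a median of −0.44 (adjusted p = 2.27e-04, and adjusted p = 0.00352 with an estimated correlation). D17H6S56E-5 rose by 3.52 (SE 0.50, adjusted p = 4.10e-05), and Mt2, Lcn2 and Mt1 by 3.36, 3.33 and 3.26. Those that fell included Saa3, a serum amyloid A gene (−2.90, SE 0.57, adjusted p = 0.00200), Hmgcs1, of sterol synthesis (−2.50, adjusted p = 0.0122), and Cyp8b1, of bile acid synthesis (−2.44, adjusted p = 0.00995). Inmt (−2.36, adjusted p = 0.0223) and the transcription factor gene Tsc22d1 (−2.19, adjusted p = 7.65e-04) also fell. Calls of Hmgcs1, Cyp8b1 and Inmt were lost without 0 h B (adjusted p = 0.0517), 0 h A (adjusted p = 0.0557) and 40 h D (adjusted p = 0.125), the last also without 0 h A or C. In all, 441 probe sets were called among 4 and 4 livers, 215 higher and 226 lower, a balance that turned to 224 and 210 with arrays centred and 241 and 196 after quantile normalization. Within PHX2, where this time had 1 liver, 3 were called, and within PHX3 402. Without the 0 h livers A and C the count was 241 and 248, and without the 40 h liver B 291.

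In Cre plus livers Mt2 and Mt1 rose and Hsd3b5 and Keg1 fell after hepatectomy at each time. Mt2 rose by 4.93 (adjusted p = 1.52e-07), 4.93 (adjusted p = 6.41e-07) and 4.27 (adjusted p = 5.64e-07) at 20, 30 and 40 h, and Mt1 by 4.77, 4.69 and 4.14. Hsd3b5 fell, with −3.46 (adjusted p = 0.00643), −3.53 (adjusted p = 0.00922, but 0.0693 without 30 h A) and −3.83 (adjusted p = 0.00179), as did Keg1, with −3.22, −3.27 and −2.97. Cidec rose by 3.75 at 20 h, a call lost without 20 h A (adjusted p = 0.109), and 16.03-fold at 30 h (adjusted p = 0.0240), a call lost without 30 h C (adjusted p = 0.0779). Lcn2 rose by 3.55 at 40 h. Hsd3b2 fell at 20 and 30 h (−3.03 and −3.27) and Inmt at 40 h (−3.23). Myc, a growth-promoting transcription factor, rose by 1.38 (SE 0.37, adjusted p = 0.0205), 1.72 (SE 0.40, adjusted p = 0.00901) and 1.32 (SE 0.35, adjusted p = 0.0196), calls lost without 20 h C (adjusted p = 0.0736), 30 h B (adjusted p = 0.0583) or 0 h C (adjusted p = 0.0651, at 40 h), and its interaction with time did not pass. Rrm2 rose by 0.93 at 20 h (adjusted p = 0.0337, but 0.189 without 20 h B), and Cdkn1a by 1.39 at 30 h (adjusted p = 0.0210, but 0.107 without 30 h C). At 40 h these core genes of the cell cycle did not pass, with 0.29 for Cdk1 (adjusted p = 0.479), 0.33 for Pcna (adjusted p = 0.305), 0.31 for Mcm5 (adjusted p = 0.562), 0.41 for Rrm2 (adjusted p = 0.371), −0.05 for Ccna2 (adjusted p = 0.794) and 0.13 for Top2a (adjusted p = 0.628). Of the 39 ribosome biogenesis factors, 17, 11 and 14 rose at 20, 30 and 40 h, with medians of 0.48, 0.33 and 0.36 (camera adjusted p = 2.26e-16, 1.01e-09 and 8.41e-13, adjusted p = 0.137, 0.297 and 0.102 with an estimated correlation). Of the 16 cholesterol synthesis genes, 11, 5 and 14 fell, with medians of −1.39, −1.13 and −1.65 (camera adjusted p = 6.49e-09, 1.19e-05 and 1.09e-11, adjusted p = 0.249, 0.435 and 0.102 with an estimated correlation). Bile acid synthesis and transport at 40 h, with 4 of 12 members lower and a median of −0.57 (camera adjusted p = 6.08e-04, and adjusted p = 0.0198 with an estimated correlation), was the only list of the 3 times called with an estimated correlation. In all, 839, 915 and 893 probe sets were called at 20, 30 and 40 h, 328, 329 and 332 of them higher, against 4 livers at 0 h and with 4, 3 and 5 livers. Within PHX2 the counts were 1, 26 and 23, and within PHX3 1017, 289 and 355. Those of 20 h shared 420 probe sets with Cre minus livers in the same direction (31.6 for independent lists), those of 30 h 178 (15.8) and those of 40 h 193 (21.4), and none was shared in opposite directions.

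Left-out livers moved the Cre plus time counts too. At 20 h the count was 530, 556, 488 and 540 without the 0 h livers A to D, and 265 and 363 without the 20 h livers A and B. At 30 h it was 494 and 562 without the 0 h livers C and D and 423 without the 30 h liver B. At 40 h it was 452, 524, 528 and 559 without the 0 h livers A to D and 494 without the 40 h liver B.

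The genotypes differed in their change from 0 h to 40 h in genes of the cell cycle. The interaction at 40 h was −3.07 for D17H6S56E-5 (SE 0.69, adjusted p = 0.0266), −2.63 for Stmn1 (SE 0.44, adjusted p = 0.00141), −2.35 for Rrm2 (SE 0.38, adjusted p = 0.00101), −2.05 for Cdc20 (SE 0.26, adjusted p = 7.13e-05), −2.01 for Cdk1 (SE 0.33, adjusted p = 0.00101), −1.87 for Mcm5 (SE 0.42, adjusted p = 0.0266), −1.39 for Pcna (SE 0.28, adjusted p = 0.00849), −1.03 for Top2a (SE 0.21, adjusted p = 0.0111) and −0.77 for Ccna2 (SE 0.13, adjusted p = 0.0015). It was called for 54 probe sets, 0 higher and 54 lower, of which 35 by at least 2-fold, but array weights called 52 higher and 133 lower. Within PHX2 1 was called and within PHX3 26, and limma gave 563 at an unadjusted p under 0.05. Of the 39 DNA replication genes 11 were lower and 28 over the list alone. Their median was −0.64 (camera adjusted p = 5.03e-44, and adjusted p = 4.24e-04 with an estimated correlation). It was −0.71 within PHX2 and −0.64 within PHX3. Of the 35 mitosis genes 19 were lower and 28 over the list alone. Their median was −0.93 (camera adjusted p = 4.17e-66, and adjusted p = 2.23e-04 with an estimated correlation). It was −0.59 within PHX2 and −1.07 within PHX3. G1 cyclins and regulators had a median of −0.25 (camera adjusted p = 2.84e-05, and adjusted p = 0.0411 with an estimated correlation), with Cdkn2c at −0.82 (adjusted p = 0.0262). At 20 h limma called 0 probe sets, with 132 at an unadjusted p under 0.05 and 462.4 expected by chance. At 30 h it called Notch1, with −0.86 (SE 0.13, adjusted p = 0.00839) and 409 probe sets at an unadjusted p under 0.05, and that call was lost without Cre plus 30 h A (adjusted p = 0.0696). Without Cre minus 0 h C the 40 h calls of D17H6S56E-5 (adjusted p = 0.0988), Mcm5 (adjusted p = 0.0988), Cdkn2c and Top2a (adjusted p = 0.0521) were lost, and the first 3 of these also without others of the 17 livers.

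Further lists were called for the interaction but lost their call with an estimated correlation. At 40 h ribosome biogenesis factors had a median of 0.26 (adjusted p = 7.36e-08, adjusted p = 0.444 with an estimated correlation). Interferon response genes had −0.32 (adjusted p = 0.00693, then 0.730) and Kupffer cell and macrophage markers −0.27 (adjusted p = 0.0240, then 0.751). Hepatocyte secreted proteins had −0.10 (adjusted p = 0.0240, then 0.667) and gluconeogenesis 0.41 (adjusted p = 0.0393, then 0.494). The last 4 also lost it on leaving out 1 liver, with p up to 0.342 (without Cre plus 0 h D), 0.314 (Cre plus 0 h A), 0.128 (Cre minus 40 h A) and 0.121 (Cre plus 40 h C). At 20 h Kupffer cell and macrophage markers had −0.38 (adjusted p = 2.85e-06, then 0.582), with 0.06 within PHX2 and −0.78 within PHX3. Fatty acid synthesis had 0.27 (adjusted p = 0.0146, then 0.582), lost without Cre plus 0 h D (adjusted p = 0.147). At 30 h DNA replication had −0.17 (adjusted p = 0.00351, then 0.719), lost without Cre minus 30 h B (adjusted p = 0.0788).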

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

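The tests of macrophage and globin transcripts, and the test of the 40 h cell cycle genes against the batches, were chosen only after the result was seen, as was the count of splits without Rps6, while the test of single arrays and the other counts of splits were chosen before.

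Kupffer cell and macrophage markers were lower in Cre plus livers at all 4 times by camera, a call held at 0 and 20 h and lost at 30 h (adjusted p = 0.292) and 40 h (adjusted p = 0.0886) with an estimated correlation. A difference between the batches is argued against by the median of the 12 members, which lay at −0.355 or lower in each batch at each time, although PHX3 held 1 Cre plus liver at 30 h and PHX2 1 Cre minus liver at 40 h. A loss of all cells other than hepatocytes is argued against by the endothelial and stellate cell lists, whose lowest median over the 4 times was −0.0056. This holds only as far as their probe sets can show a change, since the levels of these members were not checked. A lower share of macrophages in the tissue remains a candidate explanation, since at least 11 of the 12 members had a negative difference at each time. Lower expression of these genes per macrophage was not tested and stays open too.

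The globin genes Hba-a1 and Hbb-b2 were lower in Cre plus livers at 20 and 40 h. A difference between the batches is argued against by Hba-a1, whose difference nearest to 0 over both times and both batches was −1.03, in PHX2 at 20 h with 2 and 2 livers. Less blood in the sampled liver cannot be told apart from lower globin expression in blood cells. The lowest median among the platelet, neutrophil, T cell and B cell lists at 40 h was −0.080, but the median members of these lists lay at 5.62, 5.84, 5.79 and 5.62, under the array median of 5.94, where a change would be hard to see. The erythroid list, of which Hba-a1 is a member, had a mean difference of −0.45 at 20 h and −0.57 at 40 h, while its medians were −0.07 and −0.05 and its camera test did not pass.

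DNA replication and mitosis genes were lower in Cre plus livers at 40 h, and their change from 0 h differed between the genotypes. A difference between the batches is argued against by the list medians, the nearest to 0 of which was −0.77 over both lists and both batches. That value is from PHX2, which held 1 Cre minus liver at 40 h, and within PHX3, with 3 and 3 livers, the medians were −0.83 and −1.25. A single array is argued against by the mean difference nearest to 0 when any 1 array was left out, −0.892. That deletion of Rps6 holds back the rise of these genes at 40 h is a hypothesis drawn from the same data. The tests above bear on batch and single arrays and do not reach this cause. Every Cre plus liver carried the transgene as well as the deletion, so their effects cannot be told apart here. Whether Cre minus mice were injected too is not given, so an effect of the injection may be mixed in with the genotype difference. No later time was sampled, so a delay and a lasting block both stay open.

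The test of the interaction itself picked out further results. It called 1 probe set at 30 h (Notch1, −0.86) and 54 at 40 h. Among the latter were D17H6S56E-5 (−3.07), Stmn1 (−2.63), Rrm2 (−2.35), Cdc20 (−2.05), Cdk1 (−2.01), Mcm5 (−1.87), Pcna (−1.39), Top2a (−1.03) and Ccna2 (−0.77). The list medians it called at 40 h were −0.93 for mitosis, −0.64 for DNA replication and −0.25 for G1 cyclins and regulators. The others called at 40 h lost their call with an estimated correlation, 0.26 for ribosome biogenesis factors, −0.32 for interferon response, 0.41 for gluconeogenesis, −0.10 for hepatocyte secreted proteins and −0.27 for Kupffer cells and macrophages. So did those at 20 h, −0.38 for Kupffer cells and macrophages and 0.27 for fatty acid synthesis, and at 30 h, −0.17 for DNA replication.

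In 14 of 315 combinations of a named gene and a group, 1 liver lay far from the others, where 15.75 would arise by chance, which does so in about 1 in 20 groups. The gap to the nearest liver, as a share of the group's range, was 0.868 for Ccnd1 in Cre minus at 0 h (liver A) and 0.877 at 30 h (C). It was 0.754 for Cdk1 in Cre plus at 40 h (E), 0.874 for Myc in Cre plus at 20 h (C), 0.740 for Alb in Cre plus at 40 h (A) and 0.886 for Hspa5 in Cre minus at 30 h (D). It was 0.918 for Phlda3 in Cre minus at 40 h (D), 0.837 for Aldh2 in Cre minus at 40 h (A), 0.972 for Btg2 in Cre plus at 20 h (C) and 0.862 for Wdr43 in Cre minus at 30 h (C). It was 0.828 for Dipk2a in Cre plus at 40 h (E), 0.840 for Slc25a47 in Cre minus at 30 h (C), and 0.918 and 0.840 for Eif5 in Cre minus at 0 h (A) and 30 h (C). Liver C of Cre minus at 30 h accounted for 4 of the 14.

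Other splits of the same livers argued against chance for the genotype counts at 0 and 40 h, less strongly at 40 h. At 0 h 1 of 35 splits, the real one, gave as many as 6 probe sets, and the highest other gave 0. Rps6 itself is among the 6, and without its probe set 1 of 35 splits gave as many as 5, the highest other 0. That the count exceeds chance does not hold for each gene in it, and limma gave 140 probe sets at an unadjusted p under 0.05 where 462.4 are expected by chance. The spread used at 0 h was shared with later livers, which varied more, so the 140 do not measure chance alone. At 40 h 4 of 100 drawn splits, the real one included, gave as many as 495, which does not exclude chance. The highest other gave 657, with all 4 livers of 1 side and 2 of the 5 of the other from PHX3. It set Cre minus A, B and C and Cre plus B apart, so it exchanged only Cre minus D and Cre plus B. The splits did not argue against chance at 20 h, where 3 of 35 gave as many as 27. The highest other, which parted the livers exactly by batch, gave 144. The value was 1 within PHX2 and 289 within PHX3. Nor did they at 30 h, where 3 of 35 splits gave as many as 26 and the highest other, with Cre minus A, B and D and Cre plus A on the same side, gave 547. That side held all 3 livers of PHX3 and 1 of PHX2. It also parts the livers by the first principal component, on which its 4 livers lie between −10.87 and 6.85 and the other 3 between 26.52 and 30.79. The count was 2 within PHX2, 20 within PHX3 and 266 without Cre minus C. For time in Cre minus livers the splits argued against chance, with 1 of 35 at each time giving as many as 682, 290 and 441 against 2, 2 and 2 for the highest other. For time in Cre plus livers they did so too, with 1 of 35, 1 of 35 and 1 of 100 splits giving as many as 839, 915 and 893 against 5, 34 and 575. For the interaction at 40 h 3 of 100 splits gave as many as 54 and the highest other 170, which argues against chance but does not exclude it. At 30 h the splits did not argue against it, with 7 of 100 giving as many as 1 and 51 for the highest other. At 20 h the count of splits tells nothing, since the real count was 0 (132 by limma at an unadjusted p under 0.05) and 100 of 100 splits had to give as many, the highest other 43. These highest splits wholly or nearly reverse genotype at 1 of the 2 times, so that they add up genotype differences. The highest splits for genotype at 20 and 30 h, with several times the real count, point to a structure of the samples, which at 20 h runs along the batches although batch was a term of the fit. What it is at 30 h was not tested.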

How the results depend on the processing

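The fit without the 3 arrays correlating under 0.95 with their group and the fit with the first residual component as a term were chosen after the data were seen. Of the 731 gene and 416 list results, none that was called in the fit reported or in the alternative turned its direction. Changes of sign in results called in neither were not counted. The balance of counts did turn. For genotype at 40 h it went from 211 higher and 284 lower to 450 and 411 with array weights, 351 and 311 without the 3 arrays and 413 and 407 with the residual component. For genotype at 0 h it went from 4 higher and 2 lower to 1 and 2 without Cre minus B or C or Cre plus B or D. It turned in some alternatives for genotype at 30 h and for 20 and 40 h in Cre minus too. The 1 call of the 30 h interaction was a lower one, and a higher one with only the arrays compared. The Rps6 difference was called under each of the 19, 19, 18 and 20 alternatives at 0, 20, 30 and 40 h, at −4.42 to −4.15, −4.46 to −4.28, −4.68 to −4.30 and −4.17 to −4.02. Of the gene results 301 were called and 136 of these kept their call under all alternatives. Of the list results 124 were called and 19 kept their call under all, with 105 lost with an estimated correlation. Counts that moved by over 1.5 times are given below, and the cause of these moves was not tested.

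Without a batch term 17 probe sets were called for genotype at 30 h (26 in the fit reported) and 187 for 30 h in Cre minus (290). No filter gave 17 and an intensity trend 16 for genotype at 30 h. The filter at the 50th percentile gave 35 for the 40 h interaction (54). Array weights gave 55, 51, 2436 and 861 for genotype at 0, 20, 30 and 40 h (6, 27, 26 and 495), 2095, 934 and 1965 for time in Cre minus (682, 290 and 441), 2662, 3592 and 1374 for time in Cre plus (839, 915 and 893) and 1, 1587 and 185 (52 higher and 133 lower) for the interaction (0, 1 and 54, where limma gave 132 at 20 h at an unadjusted p under 0.05). Without the 3 arrays the counts were 10, 43 and 950 for genotype at 0, 20 and 30 h, 1034 and 1334 for 20 h in Cre minus and Cre plus, and 184 for the 30 h interaction. That fit had no Cre plus liver of batch PHX3 at 30 h. With the residual component they were 10, 83, 422 and 820 for genotype, 1157, 623 and 731 for time in Cre minus, 1493, 1663 and 1450 for time in Cre plus, and 45 and 91 for the interaction at 30 and 40 h. With only the arrays compared they were 26, 1, 4 and 195 for genotype, 1469, 129 and 887 for time in Cre minus, and 1472 and 322 for 30 and 40 h in Cre plus. Leaving out 1 array gave 3 to 4, 17 to 33, 4 to 266 and 295 to 537 for genotype, 331 to 768, 88 to 270 and 241 to 401 for time in Cre minus, 265 to 1118, 423 to 647 and 452 to 907 for time in Cre plus, and 0 to 1 and 37 to 69 for the interaction at 30 and 40 h.

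The replicate letters did not pair the samples: in 0 of 10 comparisons was every pair's correlation over 0.1, and they ranged from −0.499 to 0.400 with batch removed. With the letter as a replicate block, 6 probe sets were called for genotype at 30 h, and 47 gene and 4 list calls were lost and 1 and 1 gained. The mean of all Rps6 probe sets was not run as an alternative, since the array has 1.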

Other observations

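No test in this part was chosen after its result was seen, although what to describe was.

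Cyp7a1, which sets the rate of bile acid synthesis, fell after hepatectomy in both genotypes. Without sham-operated livers, its fall cannot be tied to the removal of tissue as such. In Cre minus livers its change was −2.50 at 20 h (adjusted p = 0.00638), −2.17 at 30 h (adjusted p = 0.0277) and −1.42 at 40 h, the last not past the threshold (adjusted p = 0.152). In Cre plus livers it was −1.94 (adjusted p = 0.0238), −2.23 (adjusted p = 0.0165) and −1.24 (adjusted p = 0.132). Leaving out 1 liver ended the 30 h call in Cre minus (adjusted p = 0.104, without 30 h C) and those at 20 h (adjusted p = 0.0751, without 20 h B) and 30 h (adjusted p = 0.0568, without 30 h B) in Cre plus.

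Interferon response genes had negative medians after hepatectomy in both genotypes, and few members passed in Cre minus livers. In injected mice a later time after surgery was also a later time after injection of the interferon inducer. A fading response to the injection cannot be told apart from an effect of surgery here. Of 25 members 6, 3 and 2 fell at 20, 30 and 40 h in Cre minus livers, with medians of −0.44, −0.33 and −0.36 (camera adjusted p = 7.98e-05, 2.12e-04 and 1.31e-04). In Cre plus livers 7, 4 and 12 fell, with medians of −0.58, −0.40 and −0.71 (camera adjusted p = 1.59e-06, 0.0125 and 3.79e-10). All 6 calls were lost with an estimated correlation (adjusted p = 0.361, 0.344 and 0.422 in Cre minus and 0.262, 0.734 and 0.102 in Cre plus). Leaving out 1 liver ended those at 40 h in Cre minus (adjusted p = 0.0651, without 40 h D) and at 30 h in Cre plus (adjusted p = 0.194, without 0 h D, and also without 30 h B or C). The genotypes were not shown to differ, since the 40 h interaction was lost with an estimated correlation (adjusted p = 0.730) and those at 20 and 30 h were not called. At 40 h in Cre plus livers Ifi47, an interferon-induced GTPase, fell (−1.48, adjusted p = 3.18e-04), as did Ifit1 (−1.66, adjusted p = 0.0228, but 0.122 without 0 h D).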
